A study of Homo sapiens with 27 samples.

How the data were processed

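RNA of DLD1 cells was measured by amplicon sequencing on the Ion AmpliSeq platform for human transcripts, per the labels, in 27 libraries of 9 groups with 3 replicates each. Cells were collected 72 h after transfection. The labels call the replicates biological and give each a batch equal to its replicate number, and nothing else says that they are separate cultures. Which control siRNAs make up siCTRL, and whether the total amount of siRNA was constant between groups, is not given.

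The authors' processing notes name HTSeq 0.6.0, DESeq2 1.18.1 and the hg19 genome without giving the role of each. The single deposited table holds 10470 genes in 27 columns and is named as normalized counts. Each column sums to 1000000, and between 1.0 and 6.5% of 200 low values per library lay on whole steps (tolerance 0.02) where chance gives 4.0%. The deposited values were therefore taken as TPM (tpm), in the sense of parts of a library total of 1000000, and whole reads could not be recovered. The depth per sample is unknown, so no counting error can be given and all errors come from the replicates. Lines without an identifier (2157, all empty) were left out. Of the gene identifiers, 10450 (99.81%) were found in GENCODE v29 on GRCh38, which was used for transcript sequences only. Of all 282690 values 11 are 0.

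Values were analysed as log2(TPM + 1), which understates fold changes of genes with few TPM. Genes with a mean of at least 10 TPM over all libraries were tested (6458). One limma 3.58.1 model in R 4.3.3 with a mean for each of the 9 groups, 18 residual degrees of freedom and an intensity trend in the variance prior gave log2 changes, SE and p values. These were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Genes under 10 TPM that are named come from the same model without the filter. The comparisons were the 7 knockdowns against siCTRL, siCTRL against NT, the triple against each pair knockdown, and 4 tests of departure from the sum of the single knockdowns. The median SE of a pairwise log2 change was 0.17.

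Libraries with the same replicate number resembled each other after removal of the group means (mean r of 0.355, against -0.175 for different numbers), so a model with the replicate number as a block was also fitted. Its log2 changes are identical. On simulated data with 200 changed genes in 20 simulations, the model without a block found 42.3% of 1.5-fold and 92.5% of 2-fold changes with 0.6 false calls on average, and the model with a block 74.9% and 99.4% with 8.8. For the departure of siVPS37AB from the sum these were 8.13% and 59.4% with 0.55 false calls, and with a block 28.4% and 89.3% with 7.75.

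Lists of genes (23, of which 20 had enough tested genes) were written before the data were examined, as were the groups, comparisons, tests, thresholds and the alternatives unless said otherwise. Each was tested with camera from limma at a preset correlation of 0.01 between genes, beside a correlation estimated from the data and beside fry. The median given for a list is that of its tested genes. Genes were named by a rule. VPS37A, VPS37B and VPS37C were always named. Values of 3 single genes are not reported here. For the triple knockdown against siCTRL the rule took the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 50 TPM and the same sign in all 3 same-numbered pairs. It took 5 and 5 for the pair knockdowns and for the triple against pairs, and 3 and 3 for the other comparisons. For each list it took up to 4 members with the smallest p past the threshold, or 2 as values where none passed. Some of these are left out of the text for length. PDCD6 and HSPB11 outside their own comparisons, the genes named for single omissions and the histone list were chosen after their values were seen.

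Agreement of knockdowns was measured by Pearson's r, the covariance of log2 changes and shared genes, beside 100 simulations in which unchanged groups shared the siCTRL libraries. Heptamers were ranked by the mean log2 change of genes carrying them in the 3' UTR, after removal of the trend with length and GC content, against 100 permutations of genes. Alternatives were the replicate block, a term for the number ending each library description, no filter, a mean of at least 50 TPM, a pseudocount of 8, quantile normalization, NT as reference, only the groups compared, the omission of each library, and the list tests above. Comparisons by edgeR and DESeq2, planned for counts, were not run, since they need whole reads. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for sequences, checks and figures.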

Results

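Gene expression was measured by amplicon sequencing of RNA from DLD1 cells, a human colorectal carcinoma line, 72 h after transfection with small interfering RNAs (siRNAs) against the paralogs VPS37A, VPS37B and VPS37C. Their proteins are alternative subunits of ESCRT-I, an endosomal complex that sorts ubiquitinated membrane proteins for degradation in lysosomes. The 27 libraries form 9 groups of 3 replicates: cells left untransfected (NT), cells given control siRNAs (siCTRL), and cells depleted of each paralog alone (siVPS37A, siVPS37B, siVPS37C), in pairs (siVPS37AB, siVPS37AC, siVPS37BC) or of all 3 together (siVPS37ABC). Each paralog was targeted by 1 siRNA sequence. Values are transcripts in each 1000000 (TPM) for 10470 genes, and the sequencing depth is unknown. Changes below are differences of log2(TPM + 1) with their standard error (SE) from a limma model of all libraries, n = 3 per group, for the 6458 genes with a mean of at least 10 TPM. Where a list has a camera p, the adjusted p with an estimated correlation between genes follows it, marked as estimated. Values in parentheses after an omitted replicate are the adjusted p without it. The first principal component, with 26.2% of the variance, placed all libraries of siVPS37AB, siVPS37AC and siVPS37ABC above 0 and all libraries of NT and siCTRL below 0.

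The targeted transcripts were low in every library meant to lack them. VPS37B, at 46.4 TPM in siCTRL, was at 3.35 ± 1.21% of siCTRL in siVPS37B, 4.94 ± 0.55% in siVPS37AB, 5.47 ± 2.21% in siVPS37BC and 7.42 ± 1.36% in siVPS37ABC (SD, n = 3). VPS37C, at 17.5 TPM in siCTRL, was at 21.6 ± 1.36% in siVPS37C, 23.0 ± 4.64% in siVPS37AC, 28.7 ± 2.67% in siVPS37BC and 22.7 ± 2.84% in siVPS37ABC. VPS37A had only 5.80 TPM in siCTRL, and was at 5.92 ± 1.41% in siVPS37A, 5.54 ± 2.74% in siVPS37AB, 9.11 ± 1.12% in siVPS37AC and 7.27 ± 4.02% in siVPS37ABC. In siVPS37BC, VPS37A stood at 69.4 ± 4.30% of siCTRL, which did not pass (log2 -0.43 ± 0.16, adjusted p = 0.247). Transcripts of the other ESCRT-I subunits TSG101, VPS28 and UBAP1 did not pass the test in any knockdown, the nearest being TSG101 in siVPS37AB (log2 0.40 ± 0.14, adjusted p = 0.0507). Adjusted over the 5 tested list members alone, TSG101 and UBAP1 (0.55 ± 0.19) rose in siVPS37AB (both adjusted p = 0.0131). Likewise VPS28 fell in siVPS37AC (-0.56 ± 0.19, adjusted p = 0.0180) and UBAP1 in siVPS37B (-0.48 ± 0.19, adjusted p = 0.0460), chosen after being seen. A targeted gene is among the 5, easing the adjustment.

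**Figure D1:**
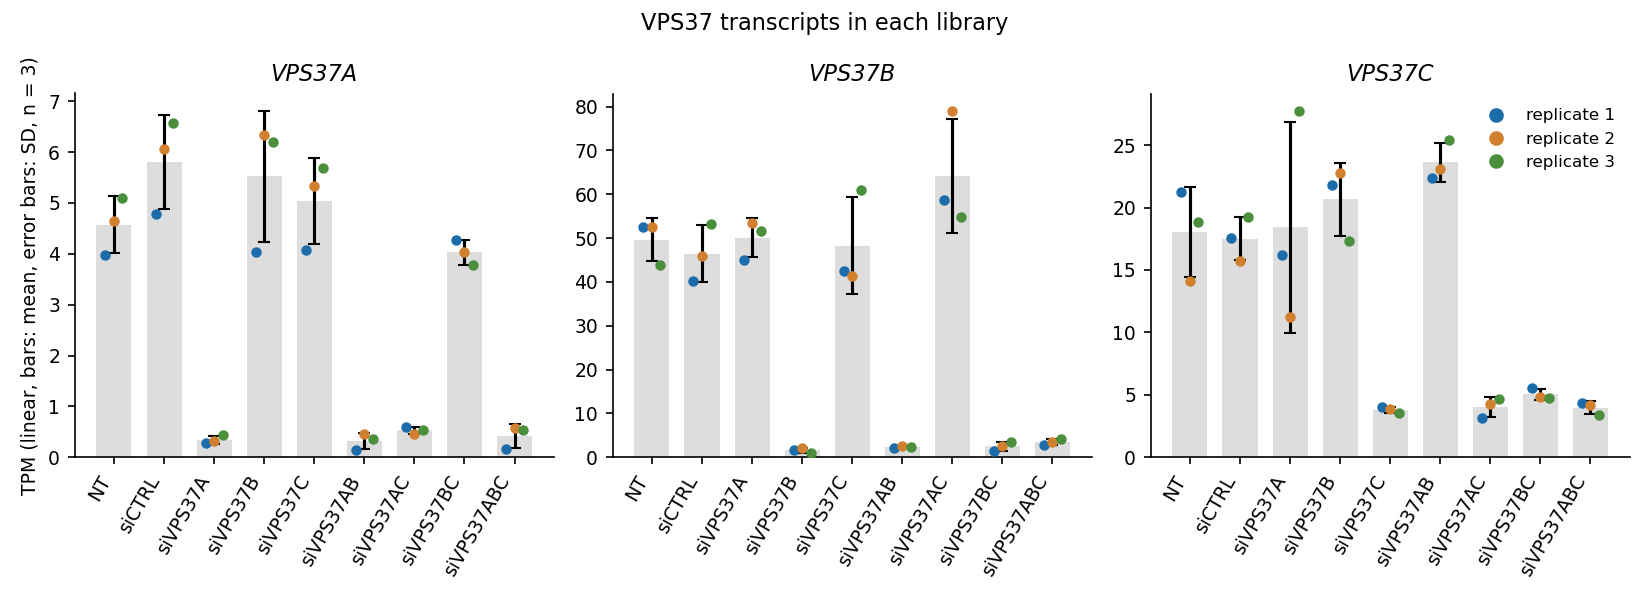
VPS37A, VPS37B and VPS37C transcripts in TPM (linear axis) in each of the 27 libraries, as points, with group means as bars and the SD of 3 replicates as error bars. VPS37B falls from a mean of 46.4 TPM in siCTRL to 3.44 TPM in siVPS37ABC, VPS37C from 17.5 to 3.98 TPM and VPS37A from 5.80 to 0.42 TPM.

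The comparison of siVPS37ABC with siCTRL asks what loss of all 3 paralogs does. IL32, a proinflammatory cytokine, rose by 2.95 ± 0.25 on the log2 scale, from 17.8 ± 5.50 to 141 ± 22.3 TPM (SD, n = 3, adjusted p = 5.53e-09). CXCL8, a neutrophil chemoattractant, rose by 2.44 ± 0.38 (adjusted p = 3.61e-05) and NFKB2, a subunit of NF-kB, by 1.67 ± 0.18 (adjusted p = 2.22e-07). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 2.74 ± 0.26 (adjusted p = 2.50e-08). It stood at 92.9 TPM against 13.6 in siCTRL and 28.8 in NT, since it was lower in siCTRL than in NT. The ribonucleotide reductase subunit RRM2, needed for DNA synthesis, fell by 1.68 ± 0.19 (adjusted p = 3.45e-07), and the linker histone gene HIST1H1D fell by 2.33 ± 0.19 (adjusted p = 5.09e-09). Among genes with a mean of at least 50 TPM and the same sign in all 3 same-numbered pairs of libraries, the other largest rises included the MAPK phosphatase DUSP5 (2.31 ± 0.20), the transcription factor BHLHE40 (2.06 ± 0.19), the tubulin TUBB3 (1.90 ± 0.23) and the keratin KRT20 (1.75 ± 0.19). The other largest falls within these limits were in the histone genes HIST1H2BM (-2.41 ± 0.21) and HIST1H3J (-1.80 ± 0.18) and the immediate early gene EGR1 (-2.38 ± 0.47, adjusted p = 5.92e-04). The troponin gene TNNC1 (-1.91 ± 0.26), the chemoattractant RARRES2 (-1.66 ± 0.20) and the matrix protein gene CYR61 (-1.61 ± 0.28) followed. Histone genes have near-identical copies, so their single values are uncertain.

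**Figure D2:**
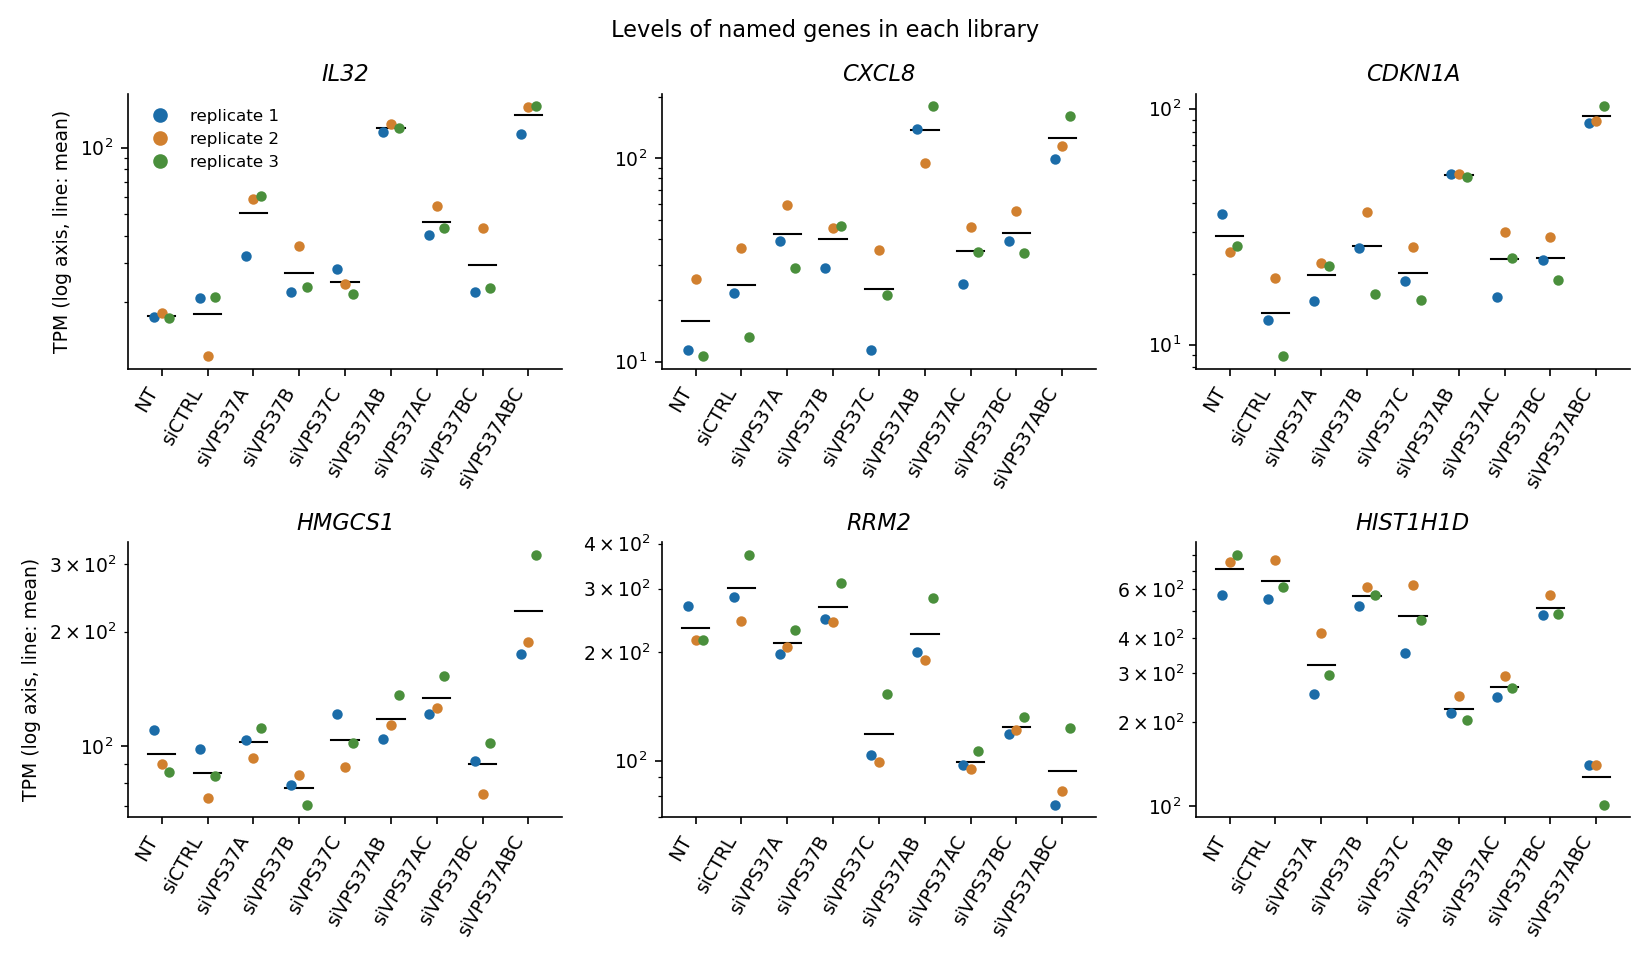
IL32, CXCL8, CDKN1A, HMGCS1, RRM2 and HIST1H1D in TPM (log axis) in each of the 27 libraries, as points by replicate number, with group means as lines. IL32 lies between 115 and 154 TPM in siVPS37ABC and between 11.4 and 21.1 TPM in siCTRL, and HIST1H1D lies between 101 and 140 TPM in siVPS37ABC and between 552 and 762 TPM in siCTRL.

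Lists of inflammatory, stress, lysosomal and cholesterol genes were higher in siVPS37ABC. With an estimated correlation the NF-kB list alone was called, and with that and the replicate number as a block the lysosome (adjusted p = 0.0159), NRF2 and cholesterol lists (both adjusted p = 0.0199) as well. Of 15 tested NF-kB targets and inflammatory cytokines, 9 rose and 0 fell, 11 and 0 adjusted over the list alone, with IL32, NFKB2, CXCL8 and the adhesion molecule ICAM1 (0.94 ± 0.15) first (median 0.81, camera adjusted p = 5.56e-07, 0.0164 estimated). CSF2 (2.11 ± 0.22, adjusted p = 1.52e-07) and TNFAIP3 (1.20 ± 0.19, adjusted p = 4.08e-05), members of the list below 10 TPM, also rose, and CD83, another of them, fell (-0.58 ± 0.17, adjusted p = 0.0159). Among 31 lysosome and autophagy genes, 11 rose and 0 fell, 13 and 0 adjusted over the list alone. They were led by the autophagy receptor SQSTM1 (1.55 ± 0.14), the sialidase NEU1 (1.26 ± 0.14) and the folliculin partner FNIP1 (1.02 ± 0.13) (median 0.39, camera adjusted p = 3.96e-06, 0.0691 estimated). The ATF4 and unfolded protein response list had 11 of 22 members up and 0 down, 12 and 0 adjusted over the list alone. Among them were the chaperones and degradation factors DNAJB9 (1.58 ± 0.21), EDEM1 (1.00 ± 0.14) and HERPUD1 (1.40 ± 0.21) (median 0.49, camera adjusted p = 2.05e-05, 0.0706 estimated). Of 13 NRF2 oxidative stress targets, 7 rose and 0 fell, 8 and 0 adjusted over the list alone. They include the peroxiredoxin repair enzyme SRXN1 (1.35 ± 0.18) and the cystine transporter SLC7A11 (1.84 ± 0.32), which is also in the ATF4 list (median 0.56, camera adjusted p = 4.03e-05, 0.0691 estimated). Cholesterol genes had 12 of 23 up and 2 down, 14 and 3 adjusted over the list alone. HMGCS1 (1.36 ± 0.18), an early enzyme of the pathway, rose, while the enzyme PMVK fell by 1.12 ± 0.22 (median 0.54, camera adjusted p = 6.27e-04, 0.119 estimated).

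The lists of S phase, mitosis, MAPK, EGFR and apoptosis genes in siVPS37ABC were called with the preset correlation but not with an estimated one. With an estimated correlation and the block, S phase (adjusted p = 0.00218) and mitosis (adjusted p = 0.0199) were called. Of 33 DNA replication and S phase genes, 0 rose and 10 fell, 0 and 13 adjusted over the list alone. First were RRM2, the thymidylate synthase TYMS (-0.68 ± 0.12) and the replication factors GINS2 (-0.70 ± 0.12) and CDT1 (-0.70 ± 0.14) (median -0.44, camera adjusted p = 2.28e-07, 0.0691 estimated). RRM2 also fell in siVPS37C, as given below. Of 28 mitosis genes, 0 rose and 7 fell, 0 and 8 adjusted over the list alone. Among these are the spindle factor TPX2 (-0.78 ± 0.12) and the chromosomal passenger protein BIRC5 (-0.76 ± 0.13) (median -0.34, camera adjusted p = 1.73e-05, 0.0691 estimated). The MAPK and AP-1 immediate early list had 9 of 16 up and 1 down, 10 and 2 adjusted over the list alone. KLF6 (1.76 ± 0.15), DUSP5 and ATF3 (1.97 ± 0.27) rose and EGR1 fell (median 0.62, camera adjusted p = 1.13e-04, 0.198 estimated). The EGFR list had 4 of 8 up and 0 down, the same adjusted over the list alone. These were EGFR (0.98 ± 0.13), its inhibitor ERRFI1 (1.41 ± 0.27) and the ligands AREG (1.28 ± 0.31) and HBEGF (0.83 ± 0.22, adjusted p = 0.0581 without siCTRL replicate 3) (median 0.57, camera adjusted p = 0.00531, 0.0691 estimated). Among 10 apoptosis regulators, 4 rose and 0 fell, 5 and 0 adjusted over the list alone. They were the proapoptotic genes BIK (1.32 ± 0.19) and PMAIP1 (adjusted p = 0.00103), the death receptor TNFRSF10A (0.75 ± 0.14) and the antiapoptotic MCL1 (0.76 ± 0.13) (median 0.41, camera adjusted p = 4.15e-04, 0.0691 estimated).

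The lists of differentiation, Wnt, ribosome biogenesis and ESCRT-I genes in siVPS37ABC were called with the preset correlation but not with an estimated one, with or without the block. Of 8 differentiation genes, 4 rose and 1 fell, 6 and 1 adjusted over the list alone, with KRT20 up and the intestinal transcription factor CDX2 (-1.30 ± 0.18) down (median 0.56, camera adjusted p = 0.0301, 0.0691 estimated). That call was lost without siCTRL replicate 3 (0.0506), siVPS37ABC replicate 2 (0.0606) or siVPS37ABC replicate 3 (0.0535). Of 8 Wnt targets and stem cell genes, 0 rose and 2 fell, the same adjusted over the list alone. They were AXIN2 (-0.92 ± 0.16), a negative feedback target of Wnt, and CCND1 (-0.64 ± 0.17) (median -0.32, camera adjusted p = 0.0162, 0.135 estimated, adjusted p = 0.0834 without siVPS37ABC replicate 3). Of 21 ribosome biogenesis genes, 0 rose and 3 fell, the same adjusted over the list alone, namely BOP1 (-0.69 ± 0.17), MYBBP1A (-0.56 ± 0.14) and NOLC1 (-0.49 ± 0.13) (median -0.24, camera adjusted p = 0.00336, 0.204 estimated). The ESCRT-I list was lower through the targeted VPS37B and VPS37C (2 of 5 down, camera adjusted p = 0.00703, 0.0691 estimated). No call was made for p53 targets (5 up and 3 down of 14, adjusted p = 0.127), although CDKN1A, SESN2 (1.13 ± 0.19) and GDF15 (1.65 ± 0.32) rose. None was made for EMT and TGF-beta targets (4 up and 2 down of 10, adjusted p = 0.181), where the integrin ITGA5 (1.37 ± 0.15) and the laminin LAMB3 (1.60 ± 0.18) rose and the matrix genes CTGF (-1.83 ± 0.30) and CYR61 fell. The interferon list (0 up and 1 down of 11, adjusted p = 0.174) held the fall of USP18 (-0.89 ± 0.15), and antigen presentation (1 up and 1 down of 9, adjusted p = 0.362) that of the immunoproteasome subunit PSMB9 (-1.14 ± 0.20). Other ESCRT components had 4 of 22 up, with CHMP2B (0.71 ± 0.15) first (adjusted p = 0.240), and housekeeping genes 1 up and 1 down of 13 (adjusted p = 0.546). Markers of fibroblasts, leukocytes and endothelium were all under 10 TPM. ACTA2 (-0.82, adjusted p = 0.0175) and CD14 (-0.96, adjusted p = 0.00461) fell, CSF1R rose (1.39, adjusted p = 1.78e-07) and EGFL7 did not pass (-0.17, adjusted p = 0.721).

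In all, 1417 of 6458 genes changed between siVPS37ABC and siCTRL at an adjusted p under 0.05, 880 up and 537 down, with 182 up and 66 down by more than 2-fold. With the replicate block the count was 2137. Quantile normalization gave a more even split of 777 up and 720 down. With NT in place of siCTRL as the reference, CYR61 (-0.53, adjusted p = 0.173), CTGF (-0.53, adjusted p = 0.205), AREG (0.54, adjusted p = 0.209) and HBEGF (0.58, adjusted p = 0.0603) were no longer called. Nor were MCL1 (0.26, adjusted p = 0.143), CCND1 (-0.44, adjusted p = 0.0630), BOP1 (-0.28, adjusted p = 0.233), USP18 (-0.36, adjusted p = 0.0839) and PSMB9 (-0.52, adjusted p = 0.0557). Of the lists, EGFR and cholesterol (both adjusted p = 0.0525), differentiation (adjusted p = 0.129) and ribosome biogenesis (adjusted p = 0.0741) were not called with NT. With a term for the number ending the library description (the library number), the MAPK (adjusted p = 0.149) and differentiation lists (adjusted p = 0.138) were not called.

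**Figure D3:**
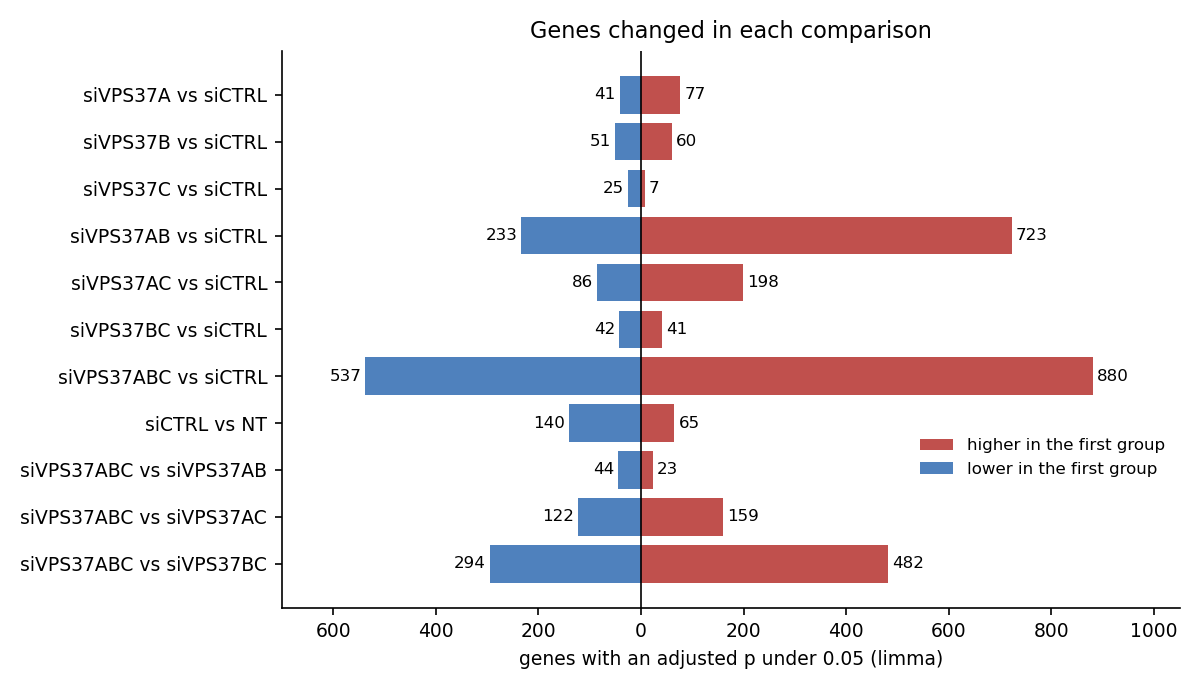
Numbers of genes with an adjusted p under 0.05 (limma, n = 3 per group) in 11 comparisons, those higher in the first group as bars to the right and those lower as bars to the left. siVPS37ABC and siVPS37AB against siCTRL have 880 and 723 genes up, and siVPS37C has 7.

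Genes of the same inflammatory list were higher in siVPS37A. In siVPS37A against siCTRL, IL32 rose by 1.45 ± 0.25 (adjusted p = 0.00154), DUSP5 by 1.16 ± 0.20 (adjusted p = 0.00154) and TUBB3 by 1.32 ± 0.23 (adjusted p = 0.00154). LCN2, an iron-binding protein of innate immunity, rose by 1.5 ± 0.32 (adjusted p = 0.0124). HIST1H2BM fell by 1.34 ± 0.21, HIST1H1D by 1.01 ± 0.19 and HIST1H3J by 0.95 ± 0.18. NF-kB targets and cytokines had 6 of 15 up and 0 down, 8 and 0 adjusted over the list alone, with NFKB2 at 0.90 ± 0.18 (median 0.61, camera adjusted p = 3.20e-08, 0.00610 estimated). The ATF4 and unfolded protein response list had 3 of 22 up and 0 down, 7 and 0 adjusted over the list alone (median 0.33, camera adjusted p = 5.24e-08, 0.0495 estimated). The 3 genes were DNAJB9 (0.85 ± 0.21, adjusted p = 0.0358), EDEM1 (0.56 ± 0.14, adjusted p = 0.0364) and the chaperone HSPA5 (0.62 ± 0.16, adjusted p = 0.0407). Among apoptosis regulators BIK alone rose of 10 (1.11 ± 0.19), 2 adjusted over the list alone (median 0.27, camera adjusted p = 3.26e-04, 0.0495 estimated). Mitosis genes were lower as a list (median -0.22, camera adjusted p = 5.24e-08, 0.0310 estimated), with TOP2A (-0.68 ± 0.17) the 1 of 28 that fell. The MAPK list was higher with the preset correlation alone (4 of 16 up, KLF6 at 0.90 ± 0.15, camera adjusted p = 7.40e-05, 0.230 estimated). So were lysosome genes (4 of 31 up, camera adjusted p = 4.93e-05, 0.152 estimated). EGFR genes were higher in that way (1 of 8 up, HBEGF at 1.15 ± 0.22, camera adjusted p = 0.00858, 0.0720 estimated), as were NRF2 targets (0 of 13, camera adjusted p = 0.00727, 0.169 estimated). S phase genes (0 of 33, camera adjusted p = 0.00121, 0.273 estimated) and housekeeping genes were lower (0 of 13, median -0.14, camera adjusted p = 0.0187, 0.0528 estimated).

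In total 118 genes changed in siVPS37A, 77 up and 41 down, or 409 with the replicate block, 458 with NT as reference, 19 with only the groups compared, and 50 up and 63 down under quantile normalization. With the block and an estimated correlation, S phase, lysosome and housekeeping genes were called (adjusted p = 0.0274, 0.0255 and 0.0322) and apoptosis regulators were not (adjusted p = 0.0860). The count was 54, 73 and 53 without siCTRL replicates 1, 2 and 3, and 50 and 65 without siVPS37A replicates 1 and 3. LCN2 lost its call without siCTRL replicate 1 (0.0578), siCTRL replicate 3 (0.0928) or siVPS37A replicate 2 (0.0669), NFKB2 without siCTRL replicate 2 (0.0610), and HBEGF without siCTRL replicate 3 (0.0502) or siVPS37A replicate 1 (0.0585). TOP2A ranged up to 0.165, lost without any siCTRL replicate or siVPS37A replicates 1 and 3. DNAJB9 (up to 0.192), EDEM1 (up to 0.132) and HSPA5 (up to 0.192) lost theirs without siCTRL replicates 1 and 3 or any siVPS37A replicate, and HSPA5 also without siCTRL replicate 2. Without siCTRL replicate 3, the MAPK (adjusted p = 0.169), EGFR (adjusted p = 0.113) and NRF2 lists (adjusted p = 0.0715) were not called, nor was NRF2 without siVPS37A replicate 2 (0.0719). With NT as reference S phase, EGFR, NRF2, apoptosis and housekeeping genes were not called (adjusted p = 0.106, 0.229, 0.0801, 0.171 and 0.0801). Housekeeping genes lost their call without siCTRL replicate 1 (0.0821), siVPS37A replicate 1 (0.0675) and siVPS37A replicate 2 (0.0950).

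In siVPS37B against siCTRL, HSPB11, an intraflagellar transport protein, fell by 1.44 ± 0.15 (adjusted p = 9.85e-07). The matrix glycoprotein THBS1 fell by 1.02 ± 0.17 (adjusted p = 0.00215) and NDUFA8, a subunit of respiratory complex I, by 1.02 ± 0.17 (adjusted p = 0.00157). In the 3' UTR, HSPB11 and NDUFA8 each have 1 site of the heptamer most depleted here, and THBS1 has 0. Within the limits of mean and sign used for siVPS37ABC, TUBB3 (1.01 ± 0.23, adjusted p = 0.0218), the aldehyde dehydrogenase ALDH3A1 (0.90 ± 0.19, adjusted p = 0.0145) and the homeobox gene HOXB8 (0.81 ± 0.21, adjusted p = 0.0439) rose most. Differentiation genes had 2 of 8 up, TFF3 (1.09 ± 0.26) and CDH17 (0.56 ± 0.14), and 4 up and 1 down adjusted over the list alone (median 0.50, camera adjusted p = 0.0115, 0.0690 estimated). Ribosome biogenesis genes were lower as a list though 0 of 21 passed (median -0.21, camera adjusted p = 0.00290, 0.436 estimated). The interferon list had STAT2, a transcription factor of interferon signalling, as 1 of 11 up (0.66 ± 0.16, camera adjusted p = 0.0139, 0.436 estimated). Higher as a list were p53 targets, with 0 of 14 past the test and 4 adjusted over the list alone (camera adjusted p = 0.0402, 0.436 estimated). S phase (0 of 33, camera adjusted p = 0.0487, 0.596 estimated) and mitosis genes were lower, with BIRC5 the 1 of 28 that fell (-0.55 ± 0.13, camera adjusted p = 0.0487, 0.520 estimated). The NF-kB list was not called, and its member CXCL5, a chemokine, fell by 0.75 ± 0.14 (adjusted p = 0.00622). In all 111 genes changed, 60 up and 51 down, or 607 with the replicate block, 267 with NT as reference, 55 with the term for the library number and 8 with only the groups compared.

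The count for siVPS37B was 41, 63 and 31 without siCTRL replicates 1, 2 and 3, and 21 and 42 without siVPS37B replicates 1 and 2. TUBB3 lost its call without siCTRL replicate 2 (0.0964), siCTRL replicate 3 (0.0712) or siVPS37B replicates 1 (0.117) and 2 (0.0648). ALDH3A1 lost it without siCTRL replicates 1 (0.0561) and 3 (0.0742) or siVPS37B replicates 1 (0.0722) and 2 (0.134), and against NT it was lower (-0.40, adjusted p = 0.262). HOXB8 lost it without any siCTRL replicate or siVPS37B replicates 1 and 2 (adjusted p from 0.0836 to 0.218), and CXCL5 without siVPS37B replicate 1 (0.0794). STAT2 (up to 0.179) lost it without any siCTRL replicate or siVPS37B replicates 1 and 2, and TFF3 (up to 0.170) without siCTRL replicates 1 and 3 or siVPS37B replicates 1 and 2. BIRC5 (up to 0.127) lost it without siCTRL replicates 1 and 3 or siVPS37B replicates 1 and 3. CDH17 (up to 0.162) lost it without any of the 6 libraries. With NT as reference the interferon, S phase, mitosis, differentiation and ribosome biogenesis lists were not called (adjusted p = 0.150, 0.358, 0.555, 0.218 and 0.202). The number of lists called, 6, was 3 without siCTRL replicate 1, 2 without siCTRL replicate 3 and 3 without siVPS37B replicate 2. The interferon list was not called without siCTRL replicate 3 (0.105) or siVPS37B replicate 1 (0.128). The p53 list was not called without siCTRL replicates 1 (0.101) and 3 (0.111) or siVPS37B replicates 2 (0.0505) and 3 (0.0890). S phase was not called without siCTRL replicates 1 (0.0800) and 3 (0.212) or siVPS37B replicate 2 (0.222), nor was mitosis (adjusted p = 0.0800, 0.105 and 0.128).

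In siVPS37C against siCTRL, RRM2 fell by 1.34 ± 0.19 (adjusted p = 3.58e-04), the ependymin-related gene EPDR1 by 0.98 ± 0.17 (adjusted p = 0.00417) and the chromatin remodeller SMARCD2 by 0.94 ± 0.16 (adjusted p = 0.00224). In the 3' UTR, RRM2 has 1 site of the second most depleted heptamer and 0 of the most depleted, and EPDR1 and SMARCD2 0 of both. The chromatin protein HMGA2 rose by 0.99 ± 0.18 (adjusted p = 0.00474) and the phosphatase subunit PPP2R1B by 0.94 ± 0.17 (adjusted p = 0.00513). The actin regulator WDR1 rose by 0.80 ± 0.13 (adjusted p = 0.00224), although against NT it stood at -0.074 (adjusted p = 0.792). Of 10 apoptosis regulators MCL1 rose (0.56 ± 0.13, adjusted p = 0.0449), also adjusted over the list alone (camera adjusted p = 0.00597, 0.117 estimated). Of 8 differentiation genes 0 passed (median 0.34, camera adjusted p = 0.0131, 0.0817 estimated), and the ESCRT-I list was lower with VPS37C itself as 1 of 5 down (camera adjusted p = 0.00597, 0.0817 estimated). In all 32 genes changed, 7 up and 25 down. The count was 134 with the replicate block, 358 with NT as reference, 60 with the term for the library number, 2 with only the groups compared, 18 without siCTRL replicate 3 and 19 without siVPS37C replicate 2. PPP2R1B lost its call without siCTRL replicate 1 (0.0539) or siVPS37C replicate 3 (0.0599), and MCL1 without any of the 6 libraries (adjusted p from 0.0614 to 0.265). The 3 list calls became 0 with NT as reference, 5 without siCTRL replicate 2 and 1 without siVPS37C replicate 1 or 2. The differentiation list was not called without siCTRL replicate 3 (0.0614) or siVPS37C replicates 1 (0.107) and 2 (0.0542), nor was the apoptosis list (adjusted p = 0.0548, 0.107 and 0.0542).

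The pair knockdowns ask whether 1 paralog is enough to keep expression near siCTRL. In siVPS37AB, where VPS37C remained, IL32 rose by 2.77 ± 0.25 (adjusted p = 2.45e-08), CXCL8 by 2.56 ± 0.38 (adjusted p = 3.89e-05) and DUSP5 by 2.36 ± 0.20 (adjusted p = 1.22e-08). The stress cytokine GDF15 rose by 1.98 ± 0.32 (adjusted p = 1.13e-04) and TUBB3 by 1.93 ± 0.23 (adjusted p = 1.94e-06). EGR1 fell by 1.96 ± 0.47 (adjusted p = 0.00602, 0.0553 without siCTRL replicate 1). HIST1H2BM (-1.62 ± 0.21), HIST1H1D (-1.52 ± 0.19), HIST1H2AJ (-1.39 ± 0.17) and HIST1H1B (-1.38 ± 0.19) fell too. NF-kB targets and cytokines had 11 of 15 up and 0 down, 13 and 0 adjusted over the list alone, with NFKB2 (1.61 ± 0.18) and the chemokine CXCL2 (1.64 ± 0.24) (median 0.83, camera adjusted p = 2.18e-09, 0.00308 estimated). The ATF4 and unfolded protein response list had 14 of 22 up and 0 down, 15 and 0 adjusted over the list alone. DNAJB9 rose by 1.84 ± 0.21 and HERPUD1 by 1.80 ± 0.21 (median 0.60, camera adjusted p = 3.60e-08, 0.0408 estimated). NRF2 targets (6 of 13 up, 9 adjusted over the list alone, SRXN1 at 1.54 ± 0.18, camera adjusted p = 9.53e-06) were higher. So were apoptosis regulators (5 of 10 up, 6 adjusted over the list alone, BIK at 1.07 ± 0.19, camera adjusted p = 3.67e-04). Mitosis genes were lower (5 of 28 down, the same adjusted over the list alone, TPX2 at -0.59 ± 0.12, camera adjusted p = 2.10e-07). For these 3 lists the adjusted p was 0.0408 with an estimated correlation.

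Other lists in siVPS37AB were called only with the preset correlation. Higher were lysosome genes (9 of 31 up, SQSTM1 at 1.41 ± 0.14, camera adjusted p = 3.10e-06, 0.0931 estimated). The MAPK list was higher too (9 up and 1 down of 16, KLF6 at 1.53 ± 0.15, camera adjusted p = 1.55e-05, 0.136 estimated). EGFR genes (4 of 8 up, EGFR at 0.65 ± 0.13, camera adjusted p = 0.00594, 0.0620 estimated) and p53 targets (5 of 14 up, CDKN1A at 1.93 ± 0.26, camera adjusted p = 0.0255, 0.108 estimated) were also higher. Lower were S phase genes (4 of 33 down, TYMS at -0.52 ± 0.12, camera adjusted p = 5.45e-07, 0.106 estimated) and ribosome biogenesis (1 of 21 down, NOLC1 at -0.45 ± 0.13, camera adjusted p = 1.38e-04, 0.108 estimated). Wnt targets were lower as well (1 of 8 down, AXIN2 at -0.62 ± 0.16, camera adjusted p = 0.00731, 0.108 estimated). In all 956 genes changed, 723 up and 233 down, with 1652 when the replicate number was a block, 531 up and 455 down under quantile normalization, and 591 and 628 without siVPS37AB replicates 1 and 3. With NT as reference EGFR genes were not called (adjusted p = 0.0813). With the block and an estimated correlation, S phase, lysosome and ribosome biogenesis genes were called (adjusted p = 0.00444, 0.0110 and 0.0173) and apoptosis regulators were not (adjusted p = 0.0646). NOLC1 lost its call without siCTRL replicates 2 (0.0553) and 3 (0.0649) or siVPS37AB replicates 1 (0.0518) and 2 (0.0623), and AXIN2 without siCTRL replicate 2 (0.0616) or siVPS37AB replicate 1 (0.0560).

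In siVPS37AC, where VPS37B remained, IL32 rose by 1.36 ± 0.25 (adjusted p = 0.00218), HMGA2 by 1.27 ± 0.18 (adjusted p = 1.60e-04) and PPP2R1B by 1.17 ± 0.17 (adjusted p = 2.84e-04). PDCD6, a calcium-binding partner of ESCRT proteins, rose by 1.14 ± 0.14 (adjusted p = 1.58e-05) but was lower than in NT (-0.70, adjusted p = 0.00122). RRM2 fell by 1.56 ± 0.19 (adjusted p = 1.58e-05), HIST1H2BM by 1.65 ± 0.21, HIST1H1D by 1.25 ± 0.19 and the nucleotide pyrophosphatase DCTPP1 by 1.05 ± 0.17. The ribosomal protein gene RPL34, which has many processed copies and is uncertain, rose by 1.32 ± 0.33 (adjusted p = 0.0199), and CYR61 fell by 1.03 ± 0.28 (adjusted p = 0.0371), though CYR61 stood at 0.05 against NT (adjusted p = 0.928). Of 23 cholesterol genes 4 rose and 1 fell, 9 and 2 adjusted over the list alone, with IDI1 (0.67 ± 0.14) up and PMVK (-1.01 ± 0.22) down (camera adjusted p = 0.0212, 0.372 estimated). The apoptosis list had 3 of 10 up, BIK (1.02 ± 0.19), TNFRSF10A (0.68 ± 0.14) and MCL1 (0.51 ± 0.13), and 4 adjusted over the list alone (camera adjusted p = 0.00228, 0.176 estimated). The NF-kB list had 4 of 15 up (CXCL5 at 0.74 ± 0.14, camera adjusted p = 0.00532, 0.209 estimated) and the MAPK list 4 of 16 (KLF6 at 0.68 ± 0.15, camera adjusted p = 0.0189, 0.449 estimated). In the lysosome list 1 of 31 rose (FNIP1 at 0.74 ± 0.13, camera adjusted p = 0.0150, 0.372 estimated). The ATF4 list had 2 of 22 up (EDEM1 at 0.56 ± 0.14, camera adjusted p = 0.0195, 0.372 estimated) and the differentiation list 2 of 8 (KRT20 at 0.76 ± 0.19, camera adjusted p = 0.0482, 0.209 estimated), though KRT20 stood at -0.30 against NT (adjusted p = 0.300). S phase genes (1 up and 1 down of 33, camera adjusted p = 0.00532) and mitosis genes (0 of 28, camera adjusted p = 0.0255) were lower as lists, each with adjusted p = 0.372 with an estimated correlation. The ESCRT-I list holds the targeted VPS37C (-1.89 ± 0.21), with a median of 0.06 but a mean of -0.36, and its call as lower (camera adjusted p = 0.0444, 0.330 estimated) was lost with the replicate block (adjusted p = 0.0865).

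In all 284 genes changed in siVPS37AC, 198 up and 86 down, 762 with the replicate block, 910 with NT as reference, 1224 with the term for the library number, and 116 up and 133 down under quantile normalization. The count was 170, 144 and 167 without siCTRL replicates 1, 2 and 3, and 165, 110 and 175 without siVPS37AC replicates 1, 2 and 3. The 10 list calls became 0 with NT as reference, 1 with the term for the library number, 4 without siCTRL replicate 3 and 6 without siVPS37AC replicate 2. RPL34 lost its call without siCTRL replicate 2 (0.167) or siVPS37AC replicates 1 (0.0991) and 2 (0.0566), and CYR61 without any siCTRL replicate or siVPS37AC replicates 2 and 3 (up to 0.200). IDI1 lost it without siVPS37AC replicate 2 (0.0503) and MCL1 without siCTRL replicates 1 and 3 or siVPS37AC replicates 1 and 3 (adjusted p up to 0.115). EDEM1 lost it without siCTRL replicates 1 and 3 or siVPS37AC replicates 2 and 3 (adjusted p up to 0.121) and KRT20 without siCTRL replicates 2 and 3 or siVPS37AC replicates 1 and 2 (adjusted p up to 0.114). Among lists, the MAPK list (adjusted p = 0.761 and 0.0680), the ATF4 list (adjusted p = 0.298 and 0.0861) and mitosis (adjusted p = 0.0937 and 0.104) were not called without siCTRL replicate 3 or siVPS37AC replicate 2. S phase was not called without siCTRL replicate 3 (0.0645). ESCRT-I was not called without siCTRL replicate 3 (0.0776) or siVPS37AC replicates 1 (0.0757) and 3 (0.0614), and differentiation not without siCTRL replicates 1 (0.0526) and 3 (0.128) or siVPS37AC replicates 1 (0.10) and 2 (0.104).

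In siVPS37BC, where VPS37A remained, NDUFA8 fell by 1.37 ± 0.17 (adjusted p = 3.41e-05), RRM2 by 1.25 ± 0.19 (adjusted p = 5.14e-04), EPDR1 by 0.94 ± 0.17 (adjusted p = 0.00425) and the deubiquitinase USP22 by 0.86 ± 0.17 (adjusted p = 0.00581). PPP2R1B rose by 1.10 ± 0.17 (adjusted p = 8.86e-04), TUBB3 by 1.15 ± 0.23 (adjusted p = 0.00662) and the chromosome condensation regulator RCC2 by 1.15 ± 0.23 (adjusted p = 0.00693). The zinc finger gene ZNF664 (0.98 ± 0.24, adjusted p = 0.0395) and the kinase LIMK1 (0.81 ± 0.20, adjusted p = 0.0369) rose and CYR61 fell (-1.22 ± 0.28, adjusted p = 0.0253). IL32 (0.69 ± 0.25, adjusted p = 0.231) and CXCL8 (0.91 ± 0.38, adjusted p = 0.317) did not pass, and the NF-kB list was not called. Of 8 differentiation genes 0 passed, and 5 were up adjusted over the list alone (median 0.47, camera adjusted p = 0.0107, 0.0430 estimated). Of 10 apoptosis regulators MCL1 rose (0.63 ± 0.13), and 2 adjusted over the list alone (camera adjusted p = 0.00749, 0.130 estimated). The ESCRT-I list was lower through VPS37B and VPS37C (2 of 5, camera adjusted p = 4.56e-05, 0.0175 estimated). With the replicate block, S phase (adjusted p = 0.0356, 0.0644 without it) and EMT genes (adjusted p = 0.0248, 0.05 without it) were called as well, but not with the block and an estimated correlation (adjusted p = 0.255 and 0.280). In that way the differentiation and ESCRT-I lists were not called either (both adjusted p = 0.0537). In all 83 genes changed, 41 up and 42 down, 283 with the replicate block, 358 with NT as reference, 155 with the term for the library number, and 33 up and 52 down under quantile normalization.

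The count for siVPS37BC was 49, 48 and 45 without siCTRL replicates 1, 2 and 3, and 32, 37 and 43 without siVPS37BC replicates 1, 2 and 3. TUBB3 lost its call without siCTRL replicate 2 (0.0632) or siVPS37BC replicate 1 (0.0583), RCC2 without the same 2 libraries (adjusted p = 0.0615 and 0.0672). USP22 lost it without siVPS37BC replicate 1 (0.0714) and MCL1 without siCTRL replicate 3 (0.0690) or siVPS37BC replicates 1 (0.0573) and 2 (0.0548). LIMK1 lost it without any of the 6 libraries (up to 0.170), ZNF664 without any of them except siCTRL replicate 2 (up to 0.199), and CYR61 without siCTRL replicates 1 and 2 or siVPS37BC replicates 2 and 3 (up to 0.161). With NT as reference differentiation and apoptosis genes were not called (both adjusted p = 0.442). The 3 list calls became 6 without siCTRL replicate 2, and 5 without siCTRL replicate 3 or siVPS37BC replicate 2.

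**Figure D4:**
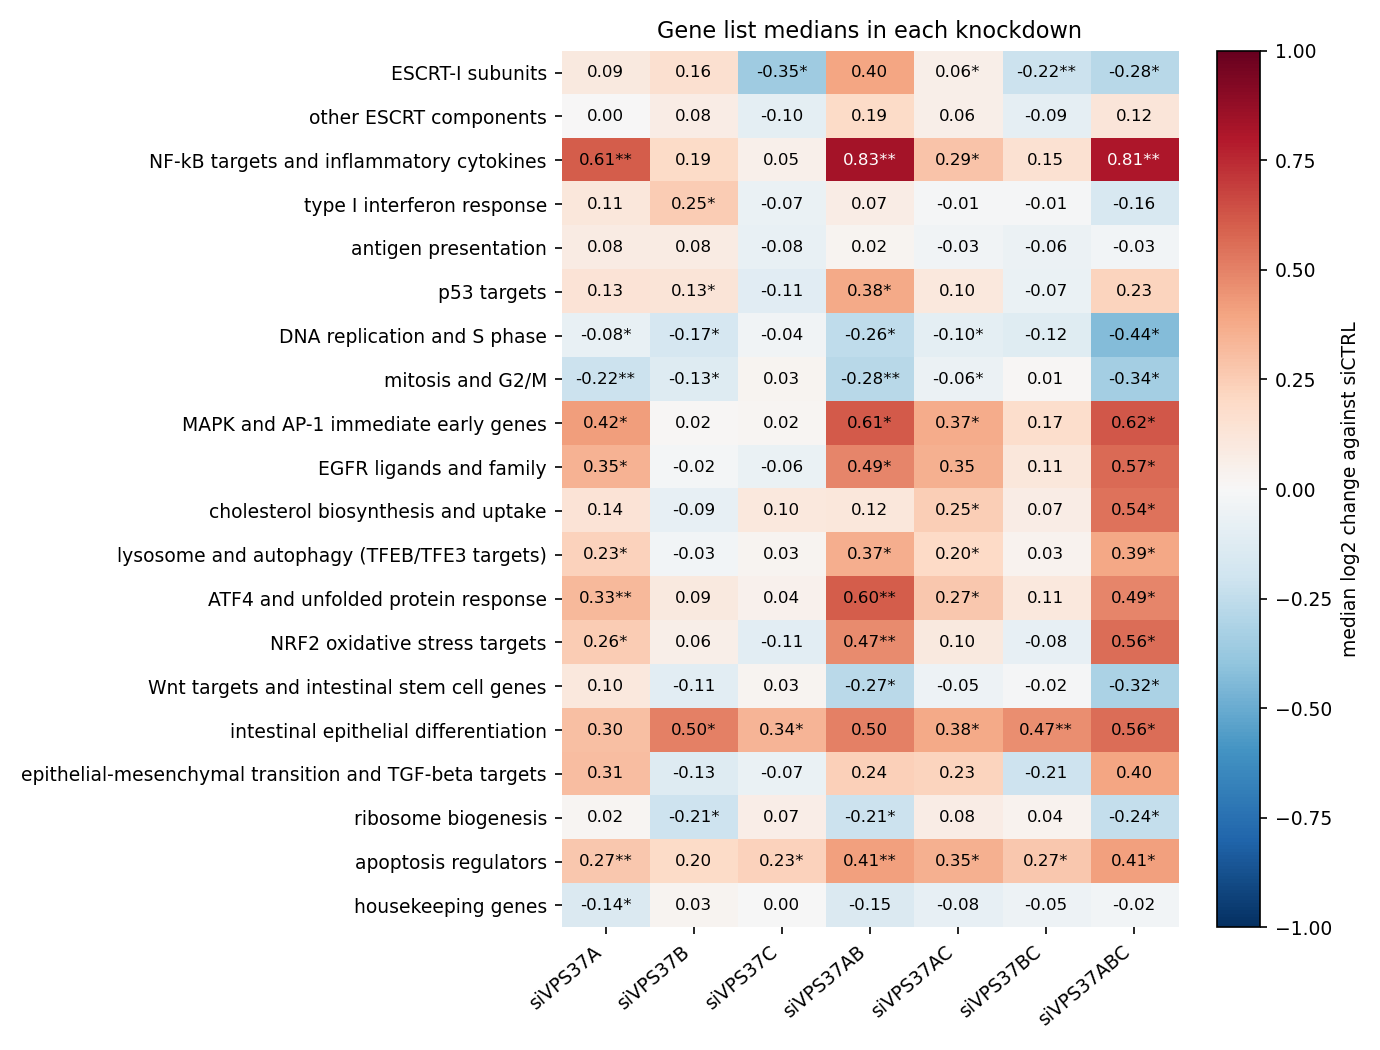
Median log2 change against siCTRL (colour, red above 0 and blue below) of 20 gene lists in the 7 knockdowns, n = 3 per group, with 1 star for a camera adjusted p under 0.05 and another where the call also holds with an estimated correlation. The NF-kB list has medians of 0.61 in siVPS37A, 0.83 in siVPS37AB and 0.81 in siVPS37ABC, and 0.15 in siVPS37BC.

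siCTRL against NT gave the joint response to transfection and control siRNAs. PDCD6 fell by 1.84 ± 0.14 (adjusted p = 2.09e-09), the lymphocyte antigen family gene LY6G6D by 1.57 ± 0.28 (adjusted p = 0.00161), ALDH3A1 by 1.30 ± 0.19 (adjusted p = 2.24e-04) and KRT20 by 1.05 ± 0.19 (adjusted p = 0.00168). In the 3' UTR, PDCD6 has 1 site of the heptamer most depleted here and ALDH3A1 0. HMGA2 rose by 1.21 ± 0.18 (adjusted p = 2.24e-04), CYR61 by 1.08 ± 0.28 (adjusted p = 0.0307), CTGF by 1.30 ± 0.30 (adjusted p = 0.0143) and the chaperone HSPA14 by 0.88 ± 0.25 (adjusted p = 0.0496). CDKN1A fell by 1.07 ± 0.26 (adjusted p = 0.0199). With camera 0 of 20 lists were called, with an estimated correlation 0 and with fry 1. Against siCTRL, PDCD6 stood at 0.37 in siVPS37A, 0.47 in siVPS37B, 0.70 in siVPS37C, 0.92 in siVPS37AB, 0.77 in siVPS37BC and 1.37 in siVPS37ABC, values looked up after they were seen. In all 205 genes changed between siCTRL and NT, 65 up and 140 down, or 572 with the replicate block, 657 with the term for the library number and 80 with only the groups compared. The count was 102 and 112 without NT replicates 1 and 3, and 119, 131 and 100 without siCTRL replicates 1, 2 and 3. The number of lists called was 2 without NT replicate 1, 1 without NT replicate 3 and 3 without siCTRL replicate 3. CDKN1A lost its call without NT replicate 1 (0.120) or siCTRL replicates 1 (0.0659) and 3 (0.161), and CTGF without NT replicate 3 (0.119) or siCTRL replicate 1 (0.0998). CYR61 lost it without any of the 6 except NT replicate 1 (up to 0.180) and HSPA14 without any of the 6 except NT replicate 2 (up to 0.234).

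The triple knockdown was set against each pair to ask what loss of the last paralog adds. Control siRNA effects may also differ, as given below. Against siVPS37AB, where VPS37C is the added loss, RRM2 fell by 1.26 ± 0.19 (adjusted p = 9.34e-04). HMGCS1 rose by 0.89 ± 0.18 (adjusted p = 0.0126) and HMGA2 by 0.97 ± 0.18 (adjusted p = 0.00791). The stress granule protein gene G3BP2 (0.83 ± 0.18) and WDR1 (0.64 ± 0.13) rose, and EPDR1 (-0.88 ± 0.17), DCTPP1 (-0.86 ± 0.17), HIST1H1D (-0.81 ± 0.19) and USP22 (-0.74 ± 0.17) fell. Cholesterol genes were higher, with 2 up, HMGCS1 among them, and PMVK (-1.07 ± 0.22) down of 23, and 9 up and 1 down adjusted over the list alone (median 0.31, camera adjusted p = 2.76e-10, 0.0358 estimated). NF-kB genes were not called, and CXCL8 stood at -0.12 ± 0.38 (adjusted p = 0.984). Lower lists were antigen presentation with PSMB9 (-1.19 ± 0.20) as 1 of 9 (camera adjusted p = 0.0203, 0.0933 estimated) and ESCRT-I with VPS37C as 1 of 5 (camera adjusted p = 0.00743, 0.0933 estimated). Lower too were interferon with 0 of 11 (camera adjusted p = 0.0238, 0.393 estimated) and S phase with RRM2 as 1 of 33 (camera adjusted p = 0.0277, 0.690 estimated). In all 67 genes changed, 23 up and 44 down, 213 with the replicate block, 128 with the term for the library number, 17 with only the groups compared, and 43 up and 28 down under quantile normalization.

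That count was 29, 11 and 29 without siVPS37AB replicates 1, 2 and 3, and 37, 34 and 28 without siVPS37ABC replicates 1, 2 and 3. HMGA2 lost its call without siVPS37AB replicate 2 (0.0511), HMGCS1 without siVPS37AB replicates 1 (0.0723) and 2 (0.0725) or siVPS37ABC replicate 3 (0.118). PMVK lost it without siVPS37AB replicates 1 and 2 or siVPS37ABC replicate 3 (up to 0.0975), DCTPP1 without siVPS37AB replicate 2 (0.0725) or siVPS37ABC replicate 3 (0.0977), and HIST1H1D without any of the 6 (up to 0.187). WDR1 (up to 0.0843) lost it without any siVPS37AB replicate or siVPS37ABC replicate 3, G3BP2 (up to 0.137) without siVPS37AB replicates 1 and 2 or siVPS37ABC replicates 2 and 3. EPDR1 (up to 0.0771) lost it without siVPS37AB replicates 2 and 3 or siVPS37ABC replicate 1, and USP22 (up to 0.163) without any siVPS37AB replicate or siVPS37ABC replicate 1. Of the 5 list calls, 3 were left without siVPS37ABC replicate 2. The interferon list was not called without siVPS37AB replicate 3 (0.0830) or siVPS37ABC replicates 2 (0.0813) and 3 (0.294), nor S phase without siVPS37AB replicate 3 (0.406) or siVPS37ABC replicate 2 (0.112).

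Against siVPS37AC, where VPS37B is the added loss, CXCL8 rose by 1.83 ± 0.38 (adjusted p = 0.00410), IL32 by 1.59 ± 0.25 (adjusted p = 3.10e-04) and DUSP5 by 1.58 ± 0.20 (adjusted p = 2.60e-05). LAMB3 rose by 1.37 ± 0.18 and the ferritin light chain gene FTL, which has processed copies, by 1.39 ± 0.22. HIST1H1D fell by 1.08 ± 0.19, NDUFA8 by 1.01 ± 0.17, RARRES2 by 0.99 ± 0.20, TNNC1 by 1.24 ± 0.26 and HIST1H2AH by 0.90 ± 0.20. NF-kB targets and cytokines had 7 of 15 up and 0 down, 9 and 1 adjusted over the list alone, with the NF-kB inhibitor TNIP1 at 0.87 ± 0.15 (median 0.65, camera adjusted p = 7.64e-07, 0.00901 estimated). NRF2 targets had 7 of 13 up and 0 down, 8 and 0 adjusted over the list alone, with SRXN1 at 1.17 ± 0.18 (median 0.63, camera adjusted p = 9.92e-10, 0.00868 estimated). With the preset correlation alone, lysosome (4 of 31 up, camera adjusted p = 3.41e-06) and ATF4 lists (5 of 22 up, camera adjusted p = 2.35e-05) were higher. So were EGFR (0 of 8, camera adjusted p = 0.0113) and p53 lists (2 of 14 up, camera adjusted p = 0.00440), all 4 with adjusted p = 0.0991 with an estimated correlation. S phase (4 of 33 down, camera adjusted p = 9.73e-07), mitosis (2 of 28 down, camera adjusted p = 2.70e-05) and ribosome biogenesis (2 of 21 down, camera adjusted p = 2.75e-05) were lower, with the same adjusted p = 0.0991 with an estimated correlation. Also called were the MAPK (4 of 16 up, camera adjusted p = 2.04e-04, 0.216 estimated) and cholesterol lists (3 of 23 up, camera adjusted p = 0.00262, 0.176 estimated). The same holds for the other ESCRT (2 of 22 up, camera adjusted p = 0.0213, 0.163 estimated) and Wnt lists (1 of 8 down, camera adjusted p = 0.0382, 0.203 estimated). With the block and an estimated correlation, p53, S phase, mitosis, cholesterol, lysosome and ribosome biogenesis genes were called (adjusted p = 0.0209, 0.00257, 0.0209, 0.0252, 0.0101 and 0.0101). In all 281 genes changed, 159 up and 122 down, 789 with the replicate block, 830 with the term for the library number, and 120, 167 and 148 without siVPS37AC replicates 1 and 3 and siVPS37ABC replicate 2. TNNC1 and HIST1H2AH lost their calls without siVPS37AC replicate 1 (both adjusted p = 0.0723), other ESCRT genes without siVPS37ABC replicate 3 (0.145), and Wnt without siVPS37AC replicates 2 (0.10) and 3 (0.0576) or siVPS37ABC replicate 3 (0.324).

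Against siVPS37BC, where VPS37A is the added loss, IL32 rose by 2.26 ± 0.25 (adjusted p = 6.11e-07), LAMB3 by 2.10 ± 0.18 (adjusted p = 1.94e-08) and DUSP5 by 2.03 ± 0.20 (adjusted p = 9.94e-08). BHLHE40 rose by 2.01 ± 0.19 (adjusted p = 8.31e-08) and SQSTM1 by 1.74 ± 0.14 (adjusted p = 7.14e-09). HIST1H1D (-2.02 ± 0.19), HIST1H2BM (-1.99 ± 0.21), HIST1H2AL (-1.53 ± 0.24), HIST1H2BE (-1.50 ± 0.19) and EGR1 (-1.47 ± 0.47, adjusted p = 0.0415) fell. NRF2 targets had 9 of 13 up and 0 down, 10 and 0 adjusted over the list alone, with SRXN1 at 1.64 ± 0.18 (median 0.76, camera adjusted p = 6.35e-09, 0.00753 estimated). NF-kB targets and cytokines had 9 of 15 up, 10 up and 1 down adjusted over the list alone, with NFKB2 at 1.52 ± 0.18 (median 0.69, camera adjusted p = 2.08e-07, 0.00753 estimated). Lysosome genes had 12 of 31 up, 17 adjusted over the list alone (camera adjusted p = 6.35e-09). EGFR genes had 4 of 8 up (camera adjusted p = 0.00255) and EMT genes 3 of 10 (camera adjusted p = 0.00195). Lysosome, EGFR and EMT genes each had adjusted p = 0.0473 with an estimated correlation. Of 28 mitosis genes 7 fell, 8 adjusted over the list alone, with TPX2 at -0.64 ± 0.12 (camera adjusted p = 2.08e-07, 0.0318 estimated). With the preset correlation alone, S phase (5 of 33 down, camera adjusted p = 3.50e-07, 0.0972 estimated), ribosome biogenesis (2 of 21 down, camera adjusted p = 2.27e-04, 0.124 estimated) were lower. Wnt genes were too (1 of 8 down, camera adjusted p = 0.0185, 0.131 estimated). Higher in that way were MAPK (7 up and 1 down of 16, camera adjusted p = 1.64e-05, 0.131 estimated) and ATF4 genes (7 of 22 up, camera adjusted p = 6.27e-06, 0.0817 estimated). Cholesterol (7 of 23 up, camera adjusted p = 2.16e-04, 0.0972 estimated) and other ESCRT genes (3 of 22 up, camera adjusted p = 0.00725, 0.0972 estimated) were higher. So were p53 (5 up and 1 down of 14, camera adjusted p = 0.0239, 0.119 estimated) and apoptosis genes (4 of 10 up, camera adjusted p = 0.0291, 0.131 estimated). With the block and an estimated correlation, other ESCRT, S phase, cholesterol and ribosome biogenesis genes were called (adjusted p = 0.0378, 0.00206, 0.00943 and 0.0187) and EMT genes were not (adjusted p = 0.123). In all 776 genes changed, 482 up and 294 down, 1447 with the replicate block and 500 without siVPS37BC replicate 1. EGR1 lost its call without siVPS37BC replicates 1 (0.229) and 2 (0.102) or siVPS37ABC replicates 2 (0.125) and 3 (0.151), p53 without siVPS37ABC replicate 1 (0.0549), Wnt without siVPS37ABC replicate 3 (0.106) and apoptosis without siVPS37BC replicate 3 (0.119) or siVPS37ABC replicate 1 (0.0907).

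Fold changes against siCTRL were compared across genes between the triple and the other knockdowns. Pearson's r of siVPS37ABC was 0.874 with siVPS37AB, 0.771 with siVPS37AC, 0.666 with siVPS37A, 0.589 with siVPS37BC, 0.450 with siVPS37C and 0.337 with siVPS37B. Genes are not independent replicates, and all use the same 3 siCTRL libraries. Unchanged groups simulated against those libraries gave an r of 0.501 and a covariance of 0.0179, against an observed covariance of 0.153 between siVPS37ABC and siVPS37AB, a difference of 0.135. siVPS37ABC and siVPS37AB shared 562 genes up and 186 down and 0 in opposite directions, where independent lists would share 98.5 and 19.4. With 3 siCTRL libraries no split left at least 2 in each part, so part of the excess may come from the shared controls.

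Each combined knockdown was tested for departure from the sum of the single ones. Joint action of paralogs was not separated from changed siRNA effects on other transcripts. HSPB11 came nearest in siVPS37AB (departure 1.14 ± 0.21, adjusted p = 0.0552), having fallen in siVPS37B but standing at -0.22 in siVPS37AB, -0.20 in siVPS37BC and 0.17 in siVPS37ABC. LAMB3 (1.32 ± 0.36, adjusted p = 0.330) and SRXN1 (1.30 ± 0.35, adjusted p = 0.330) departed upward in siVPS37ABC without passing. NRF2 targets stood above the sum in siVPS37ABC as a list, with 0 of 13 past the test and 2 adjusted over the list alone (median 0.64, camera adjusted p = 0.00498, 0.326 estimated). Interferon genes stood below it (0 of 11, median -0.41, camera adjusted p = 0.00920, 0.452 estimated). Cholesterol (0 of 23, median 0.32, camera adjusted p = 0.0306, 0.455 estimated) and lysosome genes (0 of 31, median 0.26, camera adjusted p = 0.0476, 0.504 estimated) stood above it. With the replicate block, Wnt genes were called as well (adjusted p = 0.0285, 0.0840 without it, 0.325 with the block and an estimated correlation). By limma 0 genes passed in any of the 4 tests, with 483, 250, 300 and 449 at an unadjusted p under 0.05 for siVPS37AB, siVPS37AC, siVPS37BC and siVPS37ABC. With the replicate block 33, 0, 2 and 18 passed, with the library number 0. Without single libraries, siVPS37AB had 1 gene without siCTRL replicate 1 or siVPS37B replicate 3 (HSPB11) and 4 without siVPS37A replicate 3 (MED16, TMED1, ZNF215 and SRXN1). siVPS37AC had 3 without siVPS37A replicate 3 (MED16, TMED1 and ZNF215) and 1 without siVPS37C replicate 3 (CTPS2). siVPS37BC had HSPB11 without siCTRL replicate 1 or siVPS37B replicate 3, and siVPS37ABC had ABAT without siVPS37C replicate 1 and TMEM160 without siVPS37C replicate 3. Apart from HSPB11 and SRXN1 these genes were named after their values were seen. The 4 list calls of siVPS37ABC became 2 without siVPS37A replicate 2, 1 without siVPS37B replicate 3 or siVPS37C replicate 3, and 7 without siVPS37B replicate 1 or siVPS37C replicate 1. The interferon list was not called without siCTRL replicate 3 (0.0996), nor cholesterol without siCTRL replicate 3 (0.0640), siVPS37A replicate 2 (0.0763), siVPS37B replicate 3 (0.0641) or siVPS37C replicate 3 (0.0596), nor NRF2 without siVPS37B replicate 3 (0.0641) or siVPS37C replicate 3 (0.0596). Lysosome genes were not called without siCTRL replicates 1 and 3, siVPS37A replicates 1 and 2, siVPS37B replicates 2 and 3, siVPS37C replicate 3 or siVPS37ABC replicate 3 (adjusted p from 0.0595 to 0.157).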

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

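The regroupings of libraries here were chosen only after the results were seen. The tests of departure, with and without the replicate block, were planned. Groups of 3 libraries were not tested for single outlying samples.

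Singled out here were departures, by test, of combined knockdowns from the sum of the single ones. With the replicate number as a block, 33 genes departed in siVPS37AB, where limma without the block called 0 and 483 had an unadjusted p under 0.05. Among the 33, chosen for naming after their values were seen, HSPB11 (1.14 ± 0.17, adjusted p = 0.00331) stood above the sum and LY6G6D (-1.72 ± 0.27, adjusted p = 0.00404) below it. The oxidative stress genes SRXN1 (1.24 ± 0.23, adjusted p = 0.0138), SLC7A11 (1.14 ± 0.24, adjusted p = 0.0355), GCLC (0.86 ± 0.19), NQO1 (0.84 ± 0.19, both adjusted p = 0.0370) and GSR (0.75 ± 0.18, adjusted p = 0.0472) stood above it. So did the NF-kB subunit RELB (1.04 ± 0.22, adjusted p = 0.0370). No list was tested for this departure. In siVPS37BC 2 genes departed with the block, HSPB11 (1.09 ± 0.17, adjusted p = 0.00690) and YPEL3 (-0.99 ± 0.18, adjusted p = 0.0235). In siVPS37ABC 18 departed, among them DUSP10 (1.73 ± 0.28, adjusted p = 0.00658), JAG1 (1.27 ± 0.20, adjusted p = 0.00658), HSPB11 (1.38 ± 0.24, adjusted p = 0.00993) and ZNF511 (-1.11 ± 0.20, adjusted p = 0.00993).

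As lists, without the block, NRF2 targets (median 0.64, adjusted p = 0.00498), cholesterol genes (0.32, adjusted p = 0.0306) and lysosome genes (0.26, adjusted p = 0.0476) stood above the sum in siVPS37ABC and interferon genes below it (-0.41, adjusted p = 0.00920). None of the 4 was called with an estimated correlation (adjusted p from 0.326 to 0.504), and fry called 0.

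Of 100 regroupings of the libraries for each departure test, 100 gave at least the real count of 0 by limma, as any regrouping must, so these splits decide nothing about chance. The median of the other counts was 0 in each test, and the highest was 902 for siVPS37AB, 229 for siVPS37AC, 21 for siVPS37BC and 404 for siVPS37ABC. The highest ones point to a structure of the samples, since a regrouping mixes knockdowns that differ in themselves. No biological explanation was tested for the departures.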

How the results depend on the processing

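All alternatives here were planned except no filter with the replicate block, chosen after seeing the data. The cause was not tested for any change below, except where fewer genes or fewer libraries were used by construction. DESeq2 and edgeR were not run, for lack of whole reads, and the unknown depth leaves the noise of low genes unstated. Where an omission leaves 2 libraries in a group, the spread is pooled over all groups.

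The 393 values of named genes kept direction and call in 378 cases with the replicate block (0 lost), 385 with a pseudocount of 8 (7 lost), 364 with quantile normalization (27 lost), 347 with the term for the library number (44 lost, 2 reversed) and 305 with only the groups compared (88 lost). Without a filter 385 of 392 were kept (7 lost), at a mean of at least 50 TPM 255 of 260 (3 lost), and with NT as reference 163 of 237 (59 lost, 14 reversed). Over omissions of single libraries 1960 of 2454 were kept and 488 lost. The VPS37 levels kept direction and call in all 88 alternatives and 72 omissions.

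Counts of changed genes are given in the order siVPS37A, siVPS37B, siVPS37C, siVPS37AB, siVPS37AC, siVPS37BC and siVPS37ABC against siCTRL (118, 111, 32, 956, 284, 83 and 1417), siCTRL against NT (205), and the triple against siVPS37AB, siVPS37AC and siVPS37BC (67, 281 and 776). With the replicate block they were 409, 607, 134, 1652, 762, 283, 2137, 572, 213, 789 and 1447. Without a filter and with the block they were 531, 895, 178, 2481, 1028, 416, 3205, 939, 315, 1165 and 2081. At a mean of at least 50 TPM, with fewer genes tested, they were 70, 34, 14, 379, 121, 31, 549, 65, 16, 119 and 319.

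Other alternatives moved some counts by more than 1.5 times. With NT as reference siVPS37A had 458, siVPS37B 267, siVPS37C 358, siVPS37AC 910 and siVPS37BC 358. With the term for the library number siVPS37B had 55, siVPS37C 60, siVPS37AC 1224, siVPS37BC 155, siCTRL against NT 657, and the triple against siVPS37AB 128 and against siVPS37AC 830. With only the groups compared, hence fewer libraries, siVPS37A had 19, siVPS37B 8, siVPS37C 2 (PRR9 and VPS37C, named after their values were seen), siCTRL against NT 80 and the triple against siVPS37AB 17. Without a filter siVPS37B had 179, siVPS37AB 1466, siCTRL against NT 317 and the triple against siVPS37AC 484.

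The departure tests, with 0 genes by limma, had 33 for siVPS37AB, 2 for siVPS37BC and 18 for siVPS37ABC with the block. Without a filter and with the block they had 41, 3 (COL17A1, YPEL3 and HSPB11) and 21. HSPB11 was the 1 gene for siVPS37AB and the 1 for siVPS37BC both at a mean of at least 50 TPM and with quantile normalization, and DUSP10 the 1 for siVPS37ABC with a pseudocount of 8.

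Omission of single libraries gave 50 to 132 genes for siVPS37A, 21 to 160 for siVPS37B, 18 to 23 for siVPS37C, 591 to 755 for siVPS37AB, 110 to 175 for siVPS37AC, 32 to 49 for siVPS37BC and 1078 to 1248 for siVPS37ABC. It gave 100 to 221 for siCTRL against NT, 11 to 37, 120 to 284 and 500 to 691 for the triple against siVPS37AB, siVPS37AC and siVPS37BC, and 0 to 4, 0 to 3, 0 to 1 and 0 to 1 for the departures of siVPS37AB, siVPS37AC, siVPS37BC and siVPS37ABC. The report names the libraries.

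The numbers of lists called were 10, 6, 3, 12, 10, 3 and 14 for the 7 knockdowns in that order, 0 for siCTRL against NT, 5, 13 and 15 for the triple against the pairs and 4 for its departure. With an estimated correlation they were 4 for siVPS37A, 0 for siVPS37B, siVPS37C and siVPS37AC, 5 for siVPS37AB, 1 for siVPS37ABC, 1, 2 and 6 for the triple against the pairs and 0 for its departure. With the term for the library number they were 6 for siVPS37A, 2 for siVPS37B, 1 for siVPS37C, siVPS37AC and the triple against siVPS37AB, and 2 for siCTRL against NT. With NT as reference they were 3 for siVPS37B, 0 for siVPS37C and siVPS37AC and 1 for siVPS37BC. At a mean of at least 50 TPM they were 1 for siVPS37B, 4 for siVPS37AC, 0 for siVPS37BC and 2 for the triple against siVPS37AB. With fry they were 2 for siVPS37B, 1 for siCTRL against NT, 3 for the triple against siVPS37AB and 0 for its departure. Without a filter they were 1 for siCTRL against NT and 2 for the triple against siVPS37AB, and with quantile normalization 2 for siCTRL against NT. With the block siVPS37BC had 5. Without a filter and with the block they were 1 for siVPS37C and siCTRL against NT, 3 for the triple against siVPS37AB and 8 for its departure. Omissions gave 2 to 6 for siVPS37B, 1 to 5 for siVPS37C, 4 to 11 for siVPS37AC, 3 to 6 for siVPS37BC, 0 to 3 for siCTRL against NT, 3 to 7 for the triple against siVPS37AB and 1 to 7 for its departure.

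At the preset correlation the block changed the calls of 4 lists, named in the report, and otherwise ended no call of a list or a named gene. The report gives list calls changed by the block with an estimated correlation, lost with NT or, for siVPS37ABC, lost with the library number. Without a filter siVPS37ABC also lost the differentiation list (adjusted p = 0.0632).

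Directions reversed with NT as reference for ALDH3A1 (-0.40) and CTGF (0.10) in siVPS37B, WDR1 in siVPS37C (-0.074), and CYR61 (0.054) and KRT20 (-0.30) in siVPS37AC. PDCD6 reversed in siVPS37A (-1.47), siVPS37B (-1.37), siVPS37C (-1.14), siVPS37AB (-0.92), siVPS37AC (-0.70), siVPS37BC (-1.06) and siVPS37ABC (-0.46). HSPB11, not called in either, reversed in siVPS37AB (0.27, and 0.061 with the term for the library number) and siVPS37BC (0.29 and 0.076). The MAPK list in siVPS37AC reversed with the term for the library number (adjusted p = 0.560).

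The r of siVPS37ABC with siVPS37A, siVPS37B, siVPS37C, siVPS37AB, siVPS37AC and siVPS37BC was 0.429, 0.0330, 0.272, 0.675, 0.634 and 0.342 with NT as reference for the triple, and 0.300, 0.0613, 0.0646, 0.625, 0.383 and 0.236 with NT for the other group. These remove the shared siCTRL libraries and bring in the difference of siCTRL and NT. At a mean of at least 50 TPM r was 0.710 with siVPS37A, 0.893 with siVPS37AB and 0.570 with siVPS37BC, and without a filter 0.642, 0.861 and 0.571. For siVPS37BC it was 0.577 with quantile normalization and 0.574 with a pseudocount of 8.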

Other observations

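Chosen only after the result was seen were the tests of UTR length and base composition, of heptamers between siCTRL and NT, of the number ending the library description, of NT as reference on the shared calls, of the S phase list beside the histone genes, and the splits of the libraries. The other tests were written before the values they measure were seen.

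The heptamer whose carriers in the 3' UTR were lowest was CTTAGTA in siVPS37A (z -9.06, 366 genes, mean -0.12), TTAACAA in siVPS37B (z -9.99, 759 genes, mean -0.09) and GGCGATT in siVPS37C (z -7.47, 61 genes, mean -0.20). These z are after removal of the trend with UTR length and GC content, and before it they were -9.86, -16.4 and -7.12. Against that trend as the whole cause, the least extreme z after its removal was -7.47, and each was under the lowest of 100 permutations in its comparison (-4.70, -6.58 and -5.69). The heptamers lay in the targeted transcript for 3 of 3 siRNAs, where shares in transcripts of similar length give 0.101%, and for 1 of 6 other pairs. A candidate explanation is seed pairing of the siRNAs with other transcripts. HSPB11, NDUFA8 (TTAACAA) and RRM2 (AGGCGAT, second lowest in siVPS37C) each have 1 site. HSPB11 was not called in siVPS37AB, siVPS37BC or siVPS37ABC, where TTAACAA carriers stood at -0.07, -0.05 and -0.05. Of other named falls, THBS1 has 0 sites of TTAACAA and 1 of TAACAAA (second lowest), and EPDR1 and SMARCD2 0 of both siVPS37C heptamers. The 3 siVPS37A histone genes, with no annotated 3' UTR, were not searched. With 1 siRNA per gene, paralog loss cannot be separated from seed pairing and was not tested.

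The response to the triple knockdown may also hold effects other than loss of ESCRT-I. Against 3' UTR sites of the 3 heptamers as its whole cause, 21.8% of genes without them changed (712 up, 401 down of 5097). With 1 or more it was 22.1% (143 up, 93 down of 1070). Other heptamers, coding sites and indirect effects were not counted, so wider seed effects stay open. Carriers of the 3 stood at -0.08, -0.05 and -0.15 (permutation p up to 0.0101). With the library number as a term, 1148 of 1417 calls held with the same sign. siVPS37ABC and siCTRL share only number 88, so this decides nothing. With NT as reference 939 stayed called with the same sign, between the bounds set for and against an effect of transfection or control siRNAs, so this stays open. Between siCTRL and NT the heptamer with the lowest carriers was TGACGTA (z -7.46, 71 genes, mean -0.25, lowest of the permutations -5.06), which ranked 99 before the trend was removed. PDCD6 has 1 site of it. Its carriers stood at 0.18 in siVPS37ABC against siCTRL (permutation p = 0.0015), but both comparisons use the siCTRL libraries. Sites of the antisense strands in the labels, TATCGTA and TGTCACG, were lower between siCTRL and NT by 0.07 and 0.05 (permutation p = 0.0256 and 0.0257). In the triple against the pairs their carriers had a permutation p of at least 0.132.

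Replication-dependent histone genes, 45 grouped after the data were seen, had a median of -1.15 in siVPS37ABC, with 37 down. The median was -0.79 in siVPS37AB, -0.70 in siVPS37AC, -0.65 in siVPS37A, -0.22 in siVPS37BC, -0.20 in siVPS37C and -0.03 in siVPS37B. Against transcript length and GC content as the cause, matched genes had a median of -0.11 (interval -0.20 to -0.00). Fewer cells in S phase may contribute, as the S phase list was lower in 7 of 7 comparisons with a histone median below -0.3, but in 0 with an estimated correlation. With the replicate number as a block it was lower in 7, and in 5 with the block and an estimated correlation. These comparisons share libraries of siCTRL or siVPS37ABC. The list was also lower in siVPS37B (median -0.17, adjusted p = 0.0487), where the histone median was -0.03, and in siVPS37A its median was -0.08, so this stays open. Only 17 of the 37 have an annotated 3' UTR, so the 5.41% with the siVPS37A heptamer decides nothing.

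Splits of 3 against 3 libraries number 10, too few for a share under 0.05. In each of the 11 pairwise comparisons 1 split, the real one, gave as many genes. The real counts were, in the order used above, 118, 111, 32, 956, 284, 83, 1417, 205, 67, 281 and 776. The highest other was 2 for siVPS37ABC against siVPS37AB and 0 for the rest, also among the 4 splits that part as many same-numbered pairs, the real one included.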
